A study of Mus musculus with 18 samples.

How the data were processed

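Whole hearts of mice were profiled on Affymetrix whole-genome mouse expression arrays, which measure each transcript with 1 or more sets of short oligonucleotide probes placed mostly near the 3' end of the RNA. Per the labels, mutant hearts carried floxed Pitx2 alleles together with a Cre recombinase driven by the muscle creatine kinase promoter, and control hearts carried the floxed alleles without Cre. Hearts were taken at 3, 6 and 12 weeks of age, with 3 biological replicates for each genotype and age, so that 18 arrays fell into 6 groups. Total RNA was extracted with Trizol, reverse transcribed, and copied into biotin-labelled RNA by in vitro transcription, per the labels' protocols. The sex of the animals was not stated in the labels and was not used to group arrays.

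The deposited values were intensity values on a linear scale, 1 signal for each of 45101 probe sets on each array, made with MAS5 per the submitters' processing notes. The version and settings of that software were not given in the sources used here. The signals ran from 0.1 to 71338.2. After leaving out the lowest and highest 2% of probe sets, the mean signal was 500 on every array when rounded, so the arrays share 1 trimmed mean. Arrays have no read depth, and the 3 arrays per group set the precision.

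Gene symbols came from a table of the platform's annotation, which can be old. It gave 1 symbol to 34945 probe sets, several symbols to 932 and none to 9160, besides 64 control probe sets. Only probe sets with 1 symbol were named. No probe set was assigned to Pitx2 alone in this table, so the targeted gene is not analysed here, and the genotype labels were not checked against its level.

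Signals were log2 transformed without an offset. Control probe sets were left out, probe sets in the upper 50% of mean log2 signal over all arrays were kept (a signal of about 103), and the brightest of a gene's remaining probe sets stood for the gene, which left 10883 genes. For 5056 genes more than 1 probe set passed the filter, and the report says where any of the others points the opposite way for a gene and comparison given by the naming rule. Differences were tested with limma (version 3.58.1, R 4.3.3; lmFit, then eBayes with an intensity trend, two-sided). The model had 6 group means over all 18 arrays, with 12 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The comparisons were mutant against control at each age and averaged over the 3 ages, an F test for a genotype effect that differs between the ages, and control hearts between ages. Log2 changes are printed with their standard errors (SE), and signals as mean ± SD over the 3 arrays of a group (9 for the average). A change called higher or lower without a further word passed this test.

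Beforehand, 34 gene lists with 712 symbols were written down, covering cardiac functions and markers of cell types that a heart sample could hold. Of these symbols 544 were among the genes tested, and 64 had no probe set named in the annotation used. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation between genes of 0.01, and again with a correlation estimated for each list. None of the lists passed with an estimated correlation in any comparison, so each list result holds only under the preset value, and the second p is printed beside the list results given. The genes named are, for each mutant comparison, the 6 largest rises and 6 largest falls among genes past the threshold whose mutant and control arrays do not overlap (for the average, with the same direction at all 3 ages). Where fewer passed, the lists were filled with non-overlapping genes of smallest p, said not to pass. For control hearts at 12 against 3 weeks the 5 largest in each direction were taken, for the F test the 4 smallest p, and from each list described up to 4 members. The groups, tests, lists, naming rule and first set of alternatives were chosen before the data were examined.

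The pipeline was tested on simulated data with the gene means and residual spread of the real arrays and 50 genes changed at each of 4 sizes. For mutant against control at 12 weeks it recovered 4% of genes changed by 0.3 on the log2 scale, 38% at 0.6, 80% at 1 and 96% at 1.5, and 4.39% of its calls were false. At 3 weeks it recovered 2%, 38%, 78% and 98%, at 6 weeks 4%, 38%, 78% and 94%, and for the average 32%, 82%, 96% and 100%. For the F test between ages it recovered 0%, 8%, 44% and 82%, with 8.22% of calls false. The simulated genes varied independently of each other, and the simulated arrays held no differences in RNA quality or tissue content. The shares recovered and the shares of false calls therefore need not hold for the real arrays.

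The alternatives were an offset before the log2 transformation, no filter or a stricter filter on dim probe sets, quantile normalization or median centring, all probe sets or the mean of a gene's probe sets, eBayes without a trend or with robust estimation, array weights, only the arrays of the groups compared, the replicate number as a block, 2 covariates (the log2 ratio of the 3' to the 5' Gapdh control probe set, and the log2 signal of Xist), and leaving out each array in turn. The labels state no source for a pairing by replicate number. At 12 weeks the deviations from the group means of same-numbered mutant and control arrays correlated at 0.153, 0.103 and 0.147, above the limit of 0.1. Each of these arrays correlated best with its own number. Arrays of unlike number reached 0.195 at 3 weeks and 0.275 at 6 weeks, so these values do not settle whether the numbers pair the 12-week arrays. At 3 and 6 weeks no same-numbered pair was above 0.0116. These values give no sign that the numbers pair those arrays, but with 3 arrays per group they cannot exclude it. Added after the data were seen were the 3' to 5' ratio of the Actb control probe sets as a covariate, leaving out the 3 control arrays with high Xist signal, averaging over 3 and 6 weeks only, and leaving out replicate 3 of both 3-week groups. The same samples were also split in other ways to count how often such splits call as many genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.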

Results

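The series holds expression profiles of whole hearts from mice in which floxed Pitx2 is deleted by a Cre recombinase under the muscle creatine kinase promoter, and from control mice with the floxed alleles alone. Pitx2 is a homeobox transcription factor of left-right patterning, and common variants near the human gene are associated with atrial fibrillation. Mutant and control hearts were profiled at 3, 6 and 12 weeks, with 3 arrays labelled as biological replicates in each of the 6 groups. The number of arrays limits the precision of every value. In all, 10883 genes were tested.

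The arrays differed in RNA quality by age. The ratio of 3' to 5' signal of the Actb control probe sets rises as RNA is degraded or copied incompletely. It was 1.63 ± 0.05 (SD, n = 3) in 3-week controls, 1.65 ± 0.12 in 3-week mutants, 1.54 ± 0.17 in 6-week controls and 1.66 ± 0.08 in 6-week mutants. At 12 weeks it was 2.52 ± 0.16 in mutants and 3.29 ± 0.74 in controls, and the lowest control (2.71) lay just above the highest mutant (2.69). The Gapdh ratio at 12 weeks was 0.945 ± 0.00899 in mutants and 1.16 ± 0.21 in controls, again without overlap. For each ratio a two-sided exact permutation test between the 12-week genotypes gave p = 0.1, the smallest that 3 arrays against 3 allow. The first principal component held 32.2% of the variance. On it 12-week controls lay at 36.8 ± 8.44, 12-week mutants at 11.5 ± 1.78, and the other 12 arrays between -19.8 and -4.69.

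**Figure D1:**
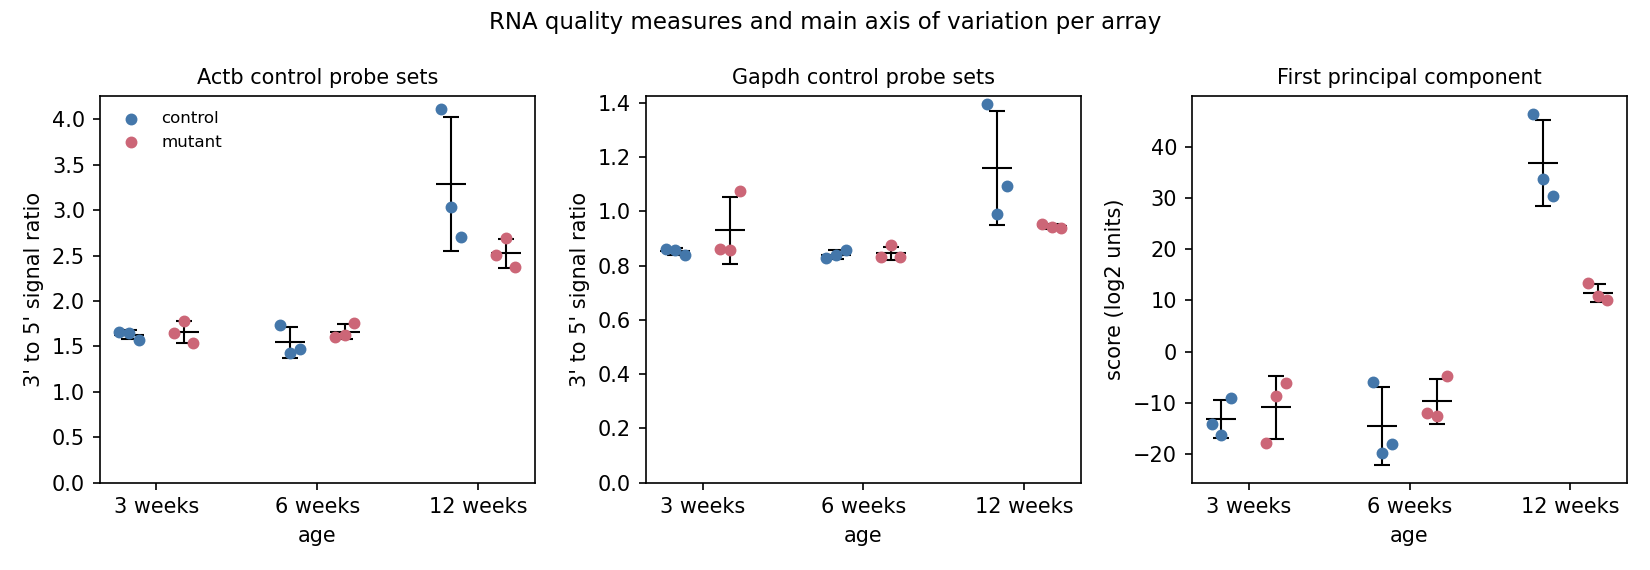
Ratio of 3' to 5' signal of the Actb and Gapdh control probe sets (no unit) and score on the first principal component of the log2 signals, for each of the 18 arrays by age and genotype. Colored points are arrays, and black marks are the group mean with its SD (n = 3); the 12-week controls lie above the 12-week mutants in each of the 3 panels.

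At 12 weeks mutant hearts carried more Bmp10, Cox8b and Gys1 transcript than control hearts. Bmp10, an atrial growth factor, was 3.04-fold higher in mutants, at 892 ± 135 against 300.5 ± 89.8 (n = 3 each, log2 change 1.61 ± 0.21 SE, limma adjusted p = 0.000732). Cox8b, a subunit of cytochrome c oxidase, was 2.43-fold higher, at 14142 ± 2191 against 5926 ± 1666. Gys1, the muscle glycogen synthase, was 2.20-fold higher. In 3-week controls Cox8b stood at 30229 ± 2366 and Bmp10 at 880 to 1034, so for both genes the 12-week controls lay below the 3-week controls. The surface glycoprotein gene Cd24a changed by -1.54 ± 0.39 on the log2 scale, and the receptor tyrosine kinase gene Ret by -1.50 ± 0.39. By limma 2128 genes passed, 1315 higher and 813 lower in mutants, of which 43 were more than 2-fold higher and 28 more than 2-fold lower. After each array was centred on its median the split was 976 higher and 976 lower.

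Of the called genes of energy metabolism more were higher than lower in 12-week mutants, beside the lower Actb and Gapdh 3' to 5' ratios of the mutant arrays. For genotype comparisons, rose and fell mean higher and lower in mutants than in controls of the same age, not a change with age. Of 58 measured genes of oxidative phosphorylation 22 rose and 2 fell, the same numbers as when adjusted over the list alone. The list had a median log2 change of 0.20 (camera adjusted p = 1.18e-05, and adjusted p = 0.864 with an estimated correlation). Cox8b (1.28 ± 0.19), the ATP synthase subunit gene Atp5l (0.85 ± 0.14) and Cox7a1 (0.68 ± 0.13) rose, and Cox7c changed by -0.74 ± 0.22, which did not pass with the replicate number as a block. Of 31 genes of fatty acid oxidation 14 rose and 1 fell, or 17 and 2 adjusted over the list alone. Among them were the acyl-CoA dehydrogenase gene Acads (0.80 ± 0.16), Mlycd (0.69 ± 0.13) and Hadha (0.65 ± 0.15), which encodes part of the trifunctional protein. This list had a median of 0.25 (camera adjusted p = 0.000776, and adjusted p = 0.864 with an estimated correlation). Of 23 genes of glycolysis and glucose uptake 11 rose and 1 fell, the same numbers as when adjusted over the list alone. Gys1 (1.14 ± 0.17), the insulin-responsive glucose transporter gene Slc2a4 (0.74 ± 0.17) and the lactate dehydrogenase gene Ldha (0.58 ± 0.09) were among those that rose. The median of the list was 0.27 (camera adjusted p = 0.00294, and adjusted p = 0.864 with an estimated correlation).

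Of the called antioxidant and ribosomal protein genes most were higher in 12-week mutants as well, beside the same differences in the ratios. Of 30 antioxidant genes 7 rose and 0 fell, or 10 and 0 adjusted over the list alone. They included the extracellular superoxide dismutase gene Sod3 (1.02 ± 0.17), the metallothionein gene Mt1 (0.70 ± 0.17) and the glutathione peroxidase gene Gpx3 (0.67 ± 0.11). The list had a median of 0.20 (camera adjusted p = 0.0126, and adjusted p = 0.864 with an estimated correlation). Without replicate 3 of the 12-week controls it did not pass (adjusted p = 0.0916, in a range of 0.000845 to 0.864 over the alternatives). Of 26 ribosomal protein genes 12 rose and 1 fell, or 14 and 1 adjusted over the list alone, with Rps15 at 0.76 ± 0.13 and Rplp2 at 0.59 ± 0.09. The median of the list was 0.24 (camera adjusted p = 0.000103, and adjusted p = 0.864 with an estimated correlation).

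Of the called genes of atrial identity and of the sarcomere most were higher in 12-week mutants, while those of the intercalated disc went both ways. Of 15 atrial identity genes 8 rose and 1 fell, the same numbers as when adjusted over the list alone. Besides Bmp10 these were, among others, sarcolipin, Sln, an inhibitor of the sarcoplasmic calcium pump (0.82 ± 0.16), Stard10 (0.76 ± 0.13) and the transcription factor gene Tbx5 (1.08 ± 0.18), whose other probe set pointed the opposite way. The atrial list had a median of 0.38 (camera adjusted p = 0.0185, and adjusted p = 0.864 with an estimated correlation). It did not pass with all probe sets (0.0863), with the mean of probe sets (0.0883) or with the Gapdh ratio as a covariate (0.132), in a range of adjusted p of 0.0072 to 0.864 over the alternatives. Of 24 sarcomere genes 6 rose and 0 fell, also when adjusted over the list alone. Myopalladin, Mypn (0.65 ± 0.10), and cardiac myosin binding protein C, Mybpc3 (0.46 ± 0.12), were among them. The median of the list was 0.25 (camera adjusted p = 0.00165, and adjusted p = 0.864 with an estimated correlation). Of 27 intercalated disc genes 4 rose and 5 fell, or 4 and 6 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.449). Desmin, Des, rose by 0.89 ± 0.13 and Xirp1 by 0.55 ± 0.14. Vinculin, Vcl, changed by -0.59 ± 0.13 and the desmosomal cadherin gene Dsg2 by -0.44 ± 0.12, but the other Vcl probe set and 3 of the 5 other Dsg2 probe sets pointed the opposite way, and with the mean of their probe sets they stood at 0.019 and 0.093.

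Genes of ion channels and transcription factors changed singly at 12 weeks. Of 20 potassium and pacemaker channel genes 5 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.329). The channel genes Kcnk3 (0.85 ± 0.12), Kcnj11 (0.70 ± 0.14) and Kcnq1 (0.54 ± 0.13) rose, and the channel gene Kcna5 changed by -0.59 ± 0.17. Of 26 genes of sodium and calcium channels and calcium handling 6 rose and 2 fell, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.449). Phospholemman, Fxyd1 (1.02 ± 0.15), the T-type calcium channel gene Cacna1h (0.63 ± 0.18) and junctophilin 2, Jph2 (0.62 ± 0.11), were among those that rose. Of 23 cardiac transcription factors and genes near atrial fibrillation loci 6 rose and 3 fell, or 7 and 5 adjusted over the list alone. Gata4 (0.79 ± 0.18) and Nkx2-5 (0.57 ± 0.14) rose, and caveolin 2, Cav2, changed by -0.66 ± 0.13. The median of this list (-0.03) and its test (down, camera adjusted p = 0.63) differed in sign from its mean (0.02).

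Stress genes and markers of other cell types also held called genes at 12 weeks, and their lists did not pass. Of 20 genes of the unfolded protein and heat shock responses 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.468). The inducible chaperone genes Hspa1b (-2.00 ± 0.69, adjusted p = 0.0496) and Hspa1a (-1.59 ± 0.51) were lower in mutants, but these calls ended in 25 and 13 of 34 alternatives. Hspa1b ranged from -2.90 to -0.71 (adjusted p from 0.00649 to 0.6) and Hspa1a from -2.20 to -0.61 (0.00665 to 0.525). Leaving out replicate 1 or 3 of the 12-week controls, or replicate 1 or 2 of the 12-week mutants, ended both, and Hspa1b was lost without any of 9 more arrays. Of 17 endothelial genes 4 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0939), with Pecam1 at 0.79 ± 0.19 and endoglin, Eng, at 0.78 ± 0.13. Of 15 macrophage genes 4 rose and 0 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.329), with the complement genes C1qc at 0.82 ± 0.18 and C1qa at 0.63 ± 0.16.

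The other genes with the largest rises at 12 weeks were Tigd5 (2.12 ± 0.42), Rusc2 (1.78 ± 0.30), 4833427F10Rik (1.76 ± 0.53), the RNA helicase gene Dhx38 (1.45 ± 0.19) and Rpl41 (1.30 ± 0.25), for which 1 of 2 other probe sets pointed the same way. The other largest falls were deoxycytidine kinase, Dck (-1.46 ± 0.33), Tent5c (-1.43 ± 0.38), Spsb4 (-1.32 ± 0.30) and the semaphorin gene Sema4b (-1.25 ± 0.40). For these and for 39.7% of all genes the 3 mutant and 3 control arrays did not overlap, where chance gives 10%. With the Gapdh or the Actb ratio as a covariate 182 and 136 genes passed, and 15 and 16 of the 65 called genes of the naming rule. With either ratio the median log2 size of the 2128 genes moved from 0.54 to 0.49 and their median SE from 0.14 to 0.18. With the replicate number as a block 1750 genes passed, and 59 of the 65. Among the other genes named at 12 weeks the calls of Sema4b, Cox7c, 4833427F10Rik, Kcna5 and Cacna1h ended in 9, 8, 7, 7 and 6 of the alternatives. The count was 1078 without replicate 1 of the 12-week controls, 977 without their replicate 3, 803 without replicate 2 of the 12-week mutants and 1153 without their replicate 3.

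Averaged over the 3 ages, mutants had more Bmp10 and endothelial Plvap and less skeletal actin. Bmp10 was 1.68-fold higher, at 1112 ± 269 against 746 ± 350 (SD, n = 9 each, log2 0.75 ± 0.12, limma adjusted p = 0.0114). Its changes were 0.17, 0.47 and 1.61 at 3, 6 and 12 weeks (F test adjusted p = 0.0221). Over 3 and 6 weeks only its average was 0.32 ± 0.15 and did not pass (adjusted p = 0.49, in a range of 0.00166 to 0.49 over the alternatives). Plvap, which forms the diaphragms of fenestrated endothelium, was 1.54-fold higher, at 725 ± 58.4 against 474 ± 72.1 (log2 0.63 ± 0.08, adjusted p = 0.00335). Acta1, the skeletal alpha-actin gene that the heart also expresses, had a log2 change of -0.76 ± 0.14, at 5750 ± 2049 against 9604 ± 2899 (adjusted p = 0.0203). Mlana (0.63 ± 0.10), the transcription factor gene Cebpd (0.60 ± 0.10), Tbkbp1 (0.59 ± 0.10) and Zfp777 (0.58 ± 0.11) rose. Decr2, a peroxisomal reductase of fatty acid oxidation (-0.70 ± 0.13), Ing5 (-0.54 ± 0.12), Itpripl2 (-0.50 ± 0.09), the collagen gene Col8a1 (-0.44 ± 0.09) and Dsg2 (-0.38 ± 0.07) fell. The naming rule took only genes with the same direction at all 3 ages, so that shared direction is no separate result. Of the 5 other Dsg2 probe sets 2 pointed the same way. In all 57 genes passed, 45 higher and 12 lower, or 19 and 10 after median centring.

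**Figure D2:**
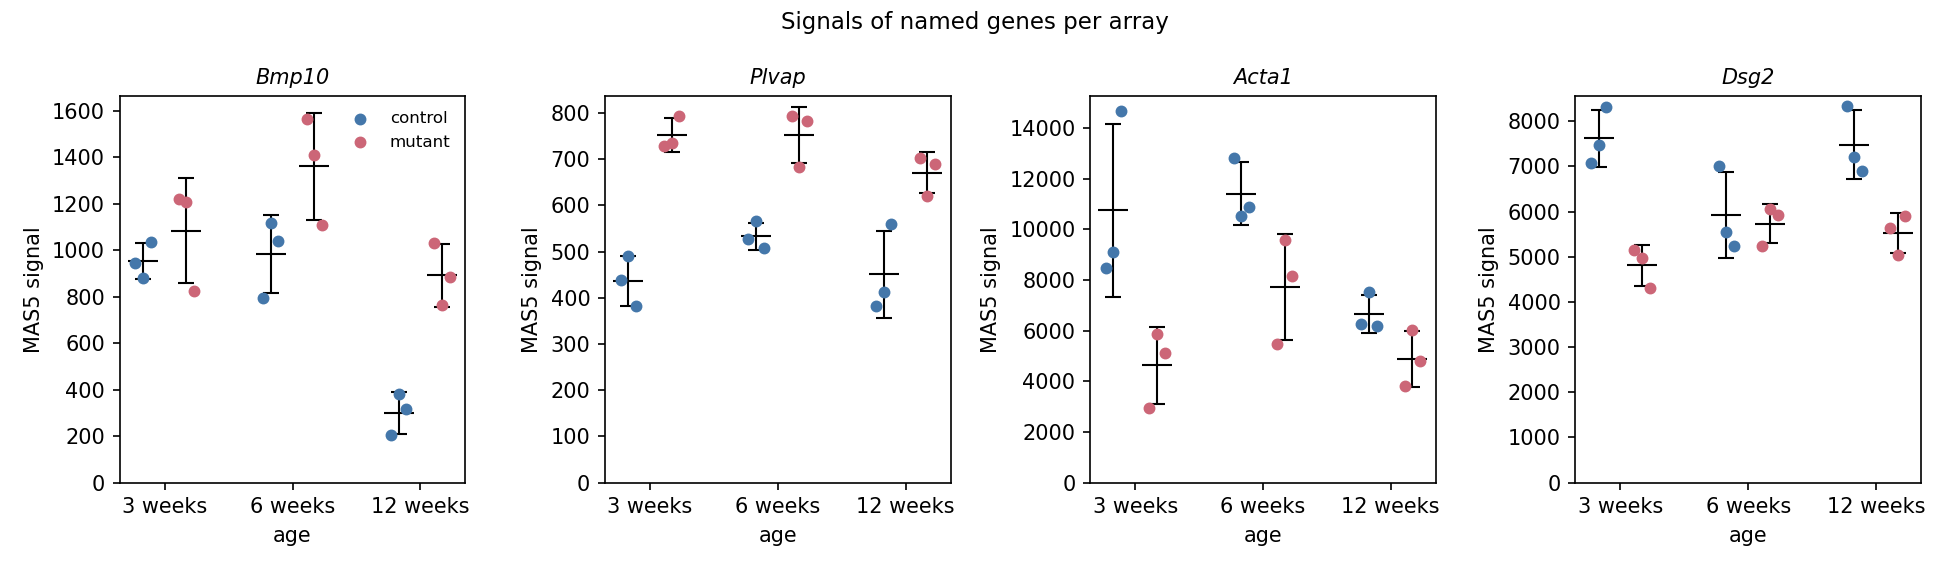
MAS5 signal (linear scale) of Bmp10, Plvap, Acta1 and Dsg2 on each of the 18 arrays by age and genotype, with arrays as colored points and the group mean with its SD (n = 3) in black. Mean Bmp10 is 300.5 in 12-week controls and 892 in 12-week mutants; Dsg2 is drawn from its brightest probe set, and the mean of its probe sets turns its average change from -0.38 to 0.036.

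The atrial identity list passed on average, with a median of 0.20 (camera adjusted p = 0.00127, and adjusted p = 0.366 with an estimated correlation). Of 15 genes 2 rose, Bmp10 and Dkk3 (0.39 ± 0.09), or 5 adjusted over the list alone. The call of Dkk3 ended in 26 of 34 alternatives, with sizes from 0.23 to 0.45. Genes of fatty acid oxidation had a median of 0.12 (camera adjusted p = 0.00128, and adjusted p = 0.978 with an estimated correlation), with 0 of 31 called, also when adjusted over the list alone. Over 3 and 6 weeks only this list did not pass (adjusted p = 0.56, in a range of 2.88e-05 to 0.978 over the alternatives). Endothelial genes had a median of 0.18 (camera adjusted p = 0.00224, and adjusted p = 0.763 with an estimated correlation), with 0 of 17 called, or 4 higher adjusted over the list alone. The ribosomal protein genes Rplp2 (0.29 ± 0.05), Rplp0 (0.28 ± 0.05) and Rpl8 (0.27 ± 0.06) rose, 3 of 26 also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.304).

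The count of the average moved more than 1.5 times in 13 of the 18 fits that left out 1 array. By limma 1 gene passed without the 3 control arrays with high Xist signal and 0 with Xist as a covariate, against 1832 genes at an unadjusted p under 0.05 in the full data, and neither kept any of the 16 called genes of the naming rule. Without these arrays Plvap stood at 0.60 ± 0.10 and Acta1 at -0.78 ± 0.18, and with the covariate at 0.58 ± 0.10 and -0.79 ± 0.19, against 0.63 ± 0.08 and -0.76 ± 0.14 in the full data. Over all alternatives Plvap ranged from 0.58 to 0.68, Mlana from 0.52 to 0.69, Cebpd from 0.49 to 0.66, Acta1 from -0.91 to -0.66 and Bmp10 from 0.32 to 0.81. With the replicate number as a block 17 genes passed, and 7 of the 16, at the same sizes, with Bmp10 (0.75 ± 0.14) not among them. With a block of the same-numbered 12-week arrays alone 52 genes passed. Of the named calls that of Dkk3 ended in 26 of 34 alternatives, those of Ing5, Col8a1 and Rpl8 in 23 each, Rplp2 in 11, Itpripl2 in 9, Zfp777 in 9 of 33, Acta1 in 8 and the others in 2 to 8. Over 3 and 6 weeks only 4 genes passed, namely Plvap (0.64 ± 0.10), Decr2 (-0.92 ± 0.16), Hnrnpl (-0.70 ± 0.12) and Psmb2 (-0.56 ± 0.10). Leaving out replicate 2 or 3 of the 3-week controls gave 20 or 29 genes, and replicate 1 or 3 of the 3-week mutants 36 or 27. Leaving out replicate 1, 2 or 3 of the 6-week controls gave 16, 155 or 20, and replicate 1 or 2 of the 6-week mutants 18 or 16. Without replicate 1 of the 12-week controls 26 passed, and without replicate 1, 2 or 3 of the 12-week mutants 35, 16 or 13.

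At 3 weeks no single gene passed, while the sarcomere and respiratory chain lists were lower in mutant hearts. The sarcomere list had a median of -0.36 (camera adjusted p = 2.89e-10, and adjusted p = 0.257 with an estimated correlation). Its member Tnnt2, cardiac troponin T, stood at 44560 in mutants against 60772 in controls (1 of 2 other probe sets opposite), and cardiac actin, Actc1, at 42324 against 57384. Genes of oxidative phosphorylation had a median of -0.27 (camera adjusted p = 5.26e-22, and adjusted p = 0.257 with an estimated correlation), with Cox6c at -0.54 ± 0.12 (its other probe set opposite) and Atp5a1 at -0.45 ± 0.11. None of the 24 and 58 genes passed over all genes, while 14 and 33 were lower, and 1 and 0 higher, when adjusted over the list alone. With quantile normalization neither list passed, with medians of -0.075 for the sarcomere (adjusted p = 0.148) and -0.017 for oxidative phosphorylation (0.352), in ranges of 3.75e-13 to 0.257 and 8.79e-29 to 0.352 over the alternatives.

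Lists of growth and vessel genes were higher in 3-week mutants. The cell cycle list had a median of 0.50 (camera adjusted p = 0.00126, and adjusted p = 0.51 with an estimated correlation), with 0 of 19 genes called, also when adjusted over the list alone. Its member Ccna2, cyclin A2, stood at 392 ± 342 against 131 ± 42.5. Without replicate 3 of the 3-week mutants the cell cycle list did not pass (adjusted p = 0.745, in a range of 2.34e-08 to 0.745), and without replicate 3 of both groups its median was -0.065. Replicate 3 of the 3-week mutants had a Gapdh 3' to 5' ratio of 1.07, while the other arrays at 3 and 6 weeks lay between 0.83 and 0.87. The imprinted growth network had a median of 0.43 (camera adjusted p = 0.00357, and adjusted p = 0.445 with an estimated correlation), with 0 of 9 genes called, or 1 higher adjusted over the list alone. Its members Plagl1 and Igf2 stood at 6977 against 4256 and 4283 against 2384. Without replicate 3 of the 3-week controls this list did not pass (adjusted p = 0.168, in a range of 0.000178 to 0.445). Endothelial genes had a median of 0.20 (camera adjusted p = 0.000837, and adjusted p = 0.257 with an estimated correlation), with 0 of 17 called, also when adjusted over the list alone, and von Willebrand factor, Vwf, at 0.38 ± 0.14. Of 29 lists tested at 3 weeks 15 passed, 4 higher and 11 lower, and 0 with an estimated correlation. Markers of skeletal muscle and of macrophages were among the 11 lower lists, and these calls ended in 9 and 18 of 35 alternatives. With quantile normalization 10 of the 11 lower lists no longer passed, while the 4 higher lists did, and with median centring 2 of the 11 no longer passed.

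The single genes at 3 weeks with the smallest p and no overlap between the groups did not pass (limma adjusted p from 0.103 to 0.171). On the higher side were Plvap (0.79 ± 0.14), galectin 3, Lgals3 (1.32 ± 0.25), Slx4 (1.08 ± 0.21), Atxn7l3 (0.54 ± 0.12), Gm13238 (1.09 ± 0.25) and the splicing factor gene Bud31 (0.41 ± 0.09). On the lower side were Dsg2 (-0.67 ± 0.12, 2 of 5 other probe sets opposite), Hoxa5 (-0.91 ± 0.18), Gcdh (-1.15 ± 0.22), cathepsin S, Ctss (-0.90 ± 0.18), 1810058I24Rik (-0.74 ± 0.15, its other probe set opposite) and Acta1, at 4636 ± 1524 against 10749 ± 3405. By limma 0 genes passed and 1317 had an unadjusted p under 0.05, where chance gives 544. With array weights 6 passed. Without replicate 1 of the 3-week mutants 19 passed, without their replicate 2 3 passed, and without replicate 3 of the 12-week controls 1.

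At 6 weeks no single gene passed either, while lists of fatty acid oxidation, atrial identity and fat cells were higher in mutants. Genes of fatty acid oxidation had a median of 0.14 (camera adjusted p = 3.05e-08, and adjusted p = 0.316 with an estimated correlation), 29 of 31 with a positive change. Angptl4, an inhibitor of lipoprotein lipase, stood at 1479 ± 290 against 568 ± 188, and the pyruvate dehydrogenase kinase gene Pdk4 at 23969 against 14419. Atrial identity genes had a median of 0.18 (camera adjusted p = 0.000281, and adjusted p = 0.279 with an estimated correlation), 14 of 15 with a positive change, and Bmp10 at 1360 ± 231 against 983 ± 170. The intercalated disc list had a median of -0.08 (camera adjusted p = 0.0092, and adjusted p = 0.316 with an estimated correlation), with ankyrin B, Ank2, at -0.44 ± 0.14. It did not pass without replicate 1 of the 6-week controls (adjusted p = 0.546), without the 3 control arrays with high Xist signal (0.487) or with Xist as a covariate (0.172), in a range of 0.000471 to 0.546 over the alternatives. Of 29 lists tested 11 passed, 8 higher and 3 lower, and 0 with an estimated correlation.

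Markers of other cell types also differed at 6 weeks, in part with single arrays. Markers of white and brown fat had a median of 0.26 (camera adjusted p = 0.0267, and adjusted p = 0.639 with an estimated correlation), 9 of 10 with a positive change. Adipoq, a hormone of fat cells named after its values were seen, stood at 4656, 6427 and 1594 on the mutant arrays and at 2231, 1271 and 3435 on the control arrays, and did not pass (0.76 ± 0.55). The fat list did not pass with no filter (adjusted p = 0.0664), without replicate 2 of the 6-week controls (0.517) or without replicate 1 or 2 of the 6-week mutants (0.308 and 0.33), in a range of 5.77e-06 to 0.639 over the alternatives. The airway secretory gene Scgb1a1, also named after its values were seen, stood at 1839, 3711 and 5.2 on the mutant arrays and at 2.4, 2.6 and 705 on the control arrays, and did not pass (4.33 ± 3.24). The 2 mutant arrays with most Scgb1a1 are replicates 1 and 2. The airway list held 2 tested genes and that of lymphocytes and neutrophils 4, too few to test, all with a positive change and with medians of 3.29 and 0.63. The fatty acid oxidation list passed under each alternative but the estimated correlation. No alternative left out replicates 1 and 2 of the 6-week mutants together or adjusted for fat or airway signal. Whether fat or airway tissue on these arrays contributes to this list was not tested. Macrophage genes had a median of 0.16 (camera adjusted p = 0.0293, and adjusted p = 0.658 with an estimated correlation). They did not pass with no filter (0.0664), with array weights (0.101), without replicate 1 or 2 of the 6-week controls (0.156 and 0.483) or without replicate 2 of the 6-week mutants (0.135), in a range of 0.000235 to 0.658. Peripheral nerve genes had a median of 0.26 (camera adjusted p = 0.0293, and adjusted p = 0.279 with an estimated correlation). They did not pass without replicate 1 or 3 of the 6-week controls (0.0818 and 0.118), without replicate 1 of the 6-week mutants (0.337), without the 3 control arrays with high Xist signal (0.428) or with Xist as a covariate (0.189), in a range of 0.00182 to 0.428. In none of the 6 lists given at 6 weeks was a gene called, also when adjusted over the list alone.

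The 6-week genes with the smallest p and no overlap did not pass (limma adjusted p from 0.559 to 0.654). On the higher side were the phagocytic receptor gene Mertk (0.57 ± 0.12), Rbp7 (0.65 ± 0.14), Btnl9 (0.48 ± 0.12), Secisbp2 (0.64 ± 0.16), Med13l (0.47 ± 0.12) and methionine synthase, Mtr (0.46 ± 0.12). On the lower side were Hnrnpl (-0.79 ± 0.17), Atp2c1 (-0.50 ± 0.11, 1 of 2 other probe sets opposite), Lrrc4b (-0.91 ± 0.22), Plk2 (-0.52 ± 0.13), Wdr1 (-0.60 ± 0.15) and Arid1b (-0.46 ± 0.11). By limma 0 genes passed and 479 had an unadjusted p under 0.05, where chance gives 544.

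**Figure D3:**
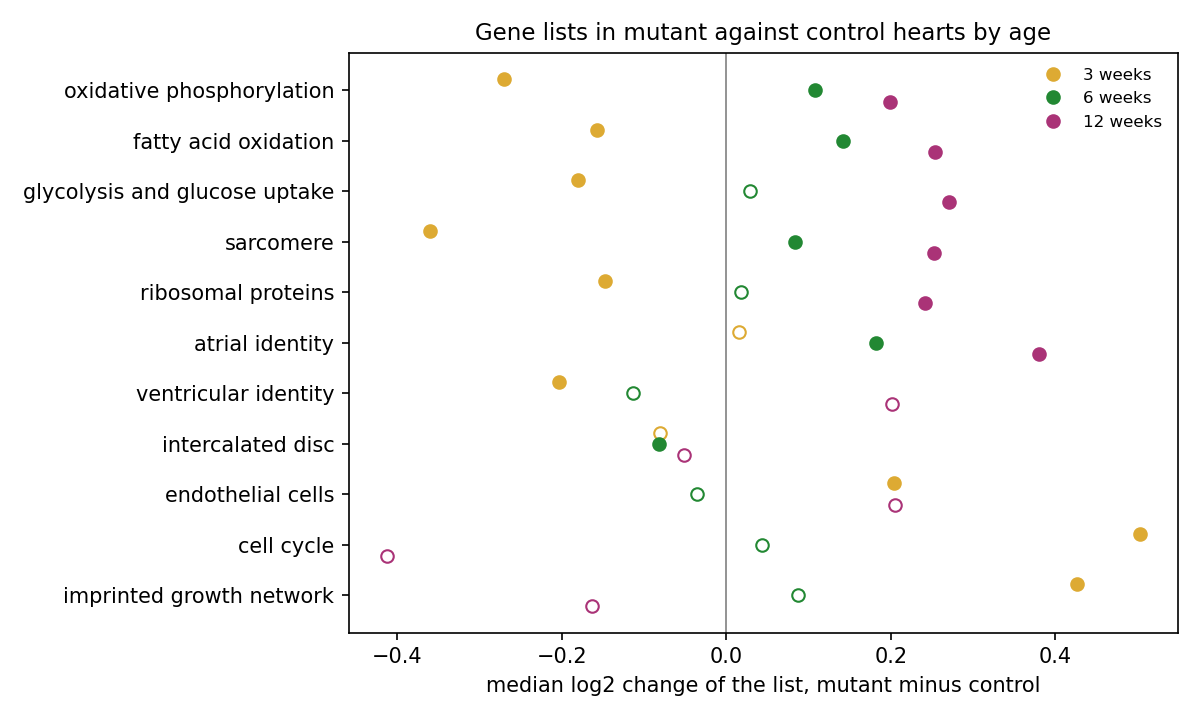
Median log2 difference between mutants and controls (x axis) of the tested genes of 11 lists (y axis) at 3, 6 and 12 weeks (n = 3 arrays per group), with filled points where camera passed at the preset correlation and hollow points where it did not; none passed with an estimated correlation. Oxidative phosphorylation lies at -0.27 at 3 weeks, or -0.017 with quantile normalization, and at 0.20 at 12 weeks, and the 6-week directions of this list and of the sarcomere in camera flip with quantile normalization.

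The genotype effect differed between the ages for genes led by Bcam, Bcat2, Bud31 and Rps10. Bcam, an adhesion molecule that binds laminin, stood at -0.39 in mutants at both 3 and 6 weeks and rose by 0.95 at 12 weeks (difference of 12 and 3 weeks 1.34 ± 0.17, limma F test adjusted p = 0.00195). Bcat2, the mitochondrial branched-chain aminotransferase, stood at -0.51 at 3 weeks and rose by 1.18 at 12 weeks (1.69 ± 0.24, adjusted p = 0.00997). Rps10 went from -0.15 to 0.91 (1.06 ± 0.16) and Bud31 from 0.41 to -0.54 (-0.95 ± 0.13). In all 560 genes passed the F test, 993 the contrast of the 12-week and 3-week effects and 369 that of the 12-week and 6-week effects. By limma 0 passed that of the 6-week and 3-week effects, where 625 had an unadjusted p under 0.05. With either 3' to 5' ratio as a covariate 0 genes passed the F test by limma, against 2793 at an unadjusted p under 0.05 without it. With the Gapdh ratio the differences of 12 and 3 weeks stood at 1.26 ± 0.22 for Bcam, 1.51 ± 0.30 for Bcat2, -0.87 ± 0.17 for Bud31 and 0.74 ± 0.16 for Rps10. With the Actb ratio they stood at 1.20 ± 0.20, 1.77 ± 0.28, -0.98 ± 0.16 and 0.98 ± 0.19. With the replicate number as a block 82 genes passed the F test, these 4 among them. With a block of the same-numbered 12-week arrays alone 651 genes passed it.

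Single arrays moved the count of the F test. It was 322 without replicate 3 of the 3-week controls, and 1001 or 330 without replicate 1 or 2 of the 3-week mutants. Without replicate 1, 2 or 3 of the 6-week controls it was 909, 341 or 355, and without replicate 2 or 3 of the 6-week mutants 341 or 365. Without replicate 1 or 3 of the 12-week controls it was 134 or 170, and without replicate 1, 2 or 3 of the 12-week mutants 328, 4 or 123.

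Across genes, which are not independent replicates, the mutant changes at 3 and 6 weeks correlated at r = 0.13, those at 3 and 12 weeks at -0.17 and those at 6 and 12 weeks at -0.09. These comparisons share no array. No gene was called at more than 1 age, since by limma 0 were called at 3 and at 6 weeks, with 1317 and 479 at an unadjusted p under 0.05. At an unadjusted p under 0.01, 3 and 6 weeks shared 22 genes in the same direction, where 1.93 would be shared by chance. The numbers were 38 against 39.3 for 3 and 12 weeks, and 9 against 9.91 for 6 and 12 weeks. The 3 control arrays with high Xist signal are all from 3 and 6 weeks, and their part in the 22 was not tested.

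Control hearts at 12 weeks had less Bmp10, Cox8b and Cdh5 transcript than control hearts at 3 weeks. Bmp10 fell from 953 ± 77.4 to 300.5 ± 89.8 (log2 -1.71 ± 0.21, limma adjusted p = 1.34e-05), Cox8b from 30229 ± 2366 to 5926 ± 1666 (-2.39 ± 0.19), and the endothelial cadherin gene Cdh5 from 1602 to 415 (-1.97 ± 0.25). Apoc1 (-2.69 ± 0.69), Rpl41 (-2.43 ± 0.25), the ribosomal gene Fau (-2.42 ± 0.15) and Rhbdf2 (-2.25 ± 0.54) also fell, but with the Actb ratio as a covariate Apoc1 and Rhbdf2 stood at 1.12 and 0.17. Gt(ROSA)26Sor (1.66 ± 0.40), Cep295 (1.63 ± 0.29), Wdr48 (1.62 ± 0.27, both other probe sets opposite), Hspbap1 (1.54 ± 0.51) and Rpf2 (1.52 ± 0.34) rose. By limma 4085 genes passed, 1910 higher and 2175 lower. After median centring the split was 2312 and 1851, and with the mean of probe sets 1202 and 2214. The 3 arrays of each group did not overlap for 45.2% of genes, where chance gives 10%. The Actb ratio rose from 1.63 to 3.29 between these groups. With it as a covariate 0 genes passed by limma, against 5072 at an unadjusted p under 0.05 without it, and with the Gapdh ratio 688. For the 4085 genes the median log2 size was 0.61 without a covariate, 0.52 with the Gapdh ratio and 0.44 with the Actb ratio, and the median SE 0.15, 0.22 and 0.36. The direction was kept by 99.7% and 88.1% of them. The 12-week control arrays are also those against which the 12-week mutants were compared.

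Of 58 genes of oxidative phosphorylation 31 fell and 2 rose between 3 and 12 weeks in controls, or 33 and 2 adjusted over the list alone, with Uqcrh at -1.24 ± 0.11. The list had a median of -0.30 (camera adjusted p = 1.52e-09, and adjusted p = 0.581 with an estimated correlation). Of 26 ribosomal protein genes 17 fell and 1 rose, or 18 and 1 adjusted over the list alone, with Rps15 at -1.43 ± 0.13. This list had a median of -0.36 (camera adjusted p = 5.76e-07, and adjusted p = 0.531 with an estimated correlation). Of 23 genes of glycolysis and glucose uptake 13 fell and 4 rose, or 15 and 4 adjusted over the list alone, with Slc2a4 at -0.72 ± 0.17 and Pfkl at -0.71 ± 0.13. Their median was -0.44 (camera adjusted p = 0.00568, and adjusted p = 0.581 with an estimated correlation). Of 24 sarcomere genes 14 fell, or 15 adjusted over the list alone, with Myom1 at -0.73 ± 0.13. Their median was -0.38 (camera adjusted p = 0.00256, and adjusted p = 0.813 with an estimated correlation), and with quantile normalization the list did not pass (adjusted p = 0.231, in a range of 2.47e-17 to 0.813).

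Of 15 atrial identity genes 9 fell in controls between 3 and 12 weeks, also when adjusted over the list alone, with the atrial myosin light chain gene Myl4 at -0.96 ± 0.12. The list had a median of -0.66 (camera adjusted p = 0.00568, and adjusted p = 0.531 with an estimated correlation). It did not pass with all probe sets (adjusted p = 0.087), the mean of probe sets (0.0829), the Gapdh ratio (0.0738) or the Actb ratio (0.252) as a covariate, in a range of 0.000368 to 0.531. Of 17 endothelial genes 9 fell and 1 rose, or 11 and 1 adjusted over the list alone, with Pecam1 at -1.77 ± 0.19. Their median was -0.44 (camera adjusted p = 0.00303, and adjusted p = 0.581 with an estimated correlation), and with the Actb ratio as a covariate the list did not pass (adjusted p = 0.605, in a range of 0.000136 to 0.605). Of 29 lists tested in this comparison 8 passed, all lower. They included markers of skeletal muscle and of macrophages, whose calls ended in 14 and 7 of 34 alternatives.

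Between 6 and 12 weeks 4450 genes passed in controls, 2086 higher and 2364 lower, or 2635 and 1895 after median centring and 1287 and 2505 with the mean of probe sets. With the Gapdh ratio as a covariate the count was 817, and with the Actb ratio it was 0 by limma, against 5388 at an unadjusted p under 0.05 without it. For the 4450 genes the median log2 size was 0.62 without a covariate, 0.53 with the Gapdh ratio and 0.42 with the Actb ratio, and the median SE 0.15, 0.23 and 0.38. Between 3 and 6 weeks 0 genes passed by limma in controls, where 561 had an unadjusted p under 0.05 and chance gives 544. The changes of all genes from 6 to 12 weeks correlated across genes at r = 0.50 between mutants and controls, which share no array. Those of the mutants correlated at 0.02 with the mutant-minus-control change at 12 weeks, although both use the 12-week mutant arrays. In both comparisons 10 genes were called in the same direction, where 24.6 would be shared by chance.

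In mutants 0 genes passed between 3 and 6 weeks by limma, with 1280 at an unadjusted p under 0.05. The count was 138 with array weights and 54 with only the groups compared. It was 1 or 4 without replicate 1 or 3 of the 3-week controls, 8 without replicate 2 of the 3-week mutants and 10 without replicate 3 of the 12-week controls. Between 6 and 12 weeks 260 genes passed in mutants, 113 higher and 147 lower, or 128 and 120 after median centring. The count was 1271 with array weights, 861 with only the groups compared, 558 with all probe sets, 123 with no filter, 101 with no trend and 146 with the replicate block. It was 163 with Xist as a covariate, 141 without the 3 arrays with high Xist signal, 27 with the Gapdh ratio and 0 with the Actb ratio by limma, against 2101 at an unadjusted p under 0.05 without it. Leaving out replicate 2 of the 3-week controls gave 168, and replicate 2 or 3 of the 3-week mutants 155 or 393. Without replicate 1, 2 or 3 of the 6-week mutants 27, 23 or 64 passed, without replicate 3 of the 12-week controls 419, and without replicate 1, 2 or 3 of the 12-week mutants 36, 38 or 100. Between 3 and 12 weeks 1220 passed, 689 higher and 531 lower, or 969 and 391 after median centring, with 2700 under array weights, 810 with no filter and 0 with the Actb ratio by limma, against 3081 at an unadjusted p under 0.05 without it. The count was 741, 750 or 724 without replicate 1, 2 or 3 of the 3-week mutants and 561, 256 or 617 without replicate 1, 2 or 3 of the 12-week mutants.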

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

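The tests of array scaling, of a larger atrial share, of RNA quality behind the atrial list and of the arrays with high Xist signal, and the counts of splits that keep same-numbered pairs apart, were chosen after the result was seen, and so were the Actb covariate and the averages or fits that leave out doubted arrays or ages. The test of RNA quality by slopes within groups and the other counts of splits were written before their results. The rule that the slope test must also lie beyond the spread of reassigned ratios was added after its value was seen.

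By a limma F test, which singled these results out, the mutant effect differed between the ages for 560 genes. In 2 of 100 splits, the real one included, as many genes passed, a share under 0.05, and the other such split gave 850. Of these 100 splits 42 part the 3 same-numbered pairs of the 12-week arrays, which the numbers may pair, 2 with as many. Of 100 splits drawn among those that part these 3 pairs 9 gave as many (highest other 1002), and 8 with a block of these pairs, where 651 genes passed (highest other 1109). In this draw 22 of the other splits kept the 12-week arrays grouped by genotype. A share above 0.05 can come from that grouping, so it does not decide on chance. Of 100 splits that part the pairs of all ages, drawn from 256, 6 gave as many (highest other 1149), and also 6 with the replicate block, where 82 passed (highest other 723). Among the named genes the effect at 12 weeks minus that at 3 weeks was 1.34 for Bcam, 1.69 for Bcat2, -0.95 for Bud31, 1.06 for Rps10, 1.46 for Dhx38, 1.78 for Gcdh, 1.69 for Rusc2, 0.61 for Ctss, 0.51 for 1810058I24Rik, 1.44 for Bmp10, 1.74 for Rpl41, -1.71 for Gm13238, 0.98 for Hoxa5, 2.33 for Tigd5 and -2.21 for Tent5c. For the average over the ages 2 of 100 splits, the real one included, gave as many genes, with 57 in the real grouping and 254 in the other. Of the 42 that part the 12-week pairs 2 gave as many. Of the 100 drawn among such splits 5 did (highest other 902), and also 5 with a block of these pairs, where 52 genes passed (highest other 1078). Again 22 of the other splits kept the 12-week grouping by genotype, so this share does not decide on chance either. Of the 100 that part the pairs of all ages 8 gave as many (highest other 1584), and 6 with the replicate block, where 17 passed (highest other 1328). Splits with several times the real count can point to a structure of the samples, or to a grouping by genotype that they keep. In both tests each other split with as many genes kept the 12-week arrays grouped by genotype, and without that grouping no split gave more than 2 genes. The 12-week grouping by genotype is also one by RNA quality, since neither the Actb nor the Gapdh ratio overlapped between these groups. The splits therefore cannot tell an effect of genotype from one of RNA quality.

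The 12-week mutants differed from the 12-week controls in 2128 genes, and the arrays of these groups also differed in RNA quality. Centring each array on its median kept 1789 of the called genes in the same direction, 84.1%. The arrays already shared 1 trimmed mean, and their median log2 signals were 9.38 to 9.42 in controls and 9.44 to 9.46 in mutants. Centring therefore moved changes little against the median called size of 0.54, and it does not decide on scaling. If RNA quality were the cause, slopes of signal on the Actb ratio within the 12-week groups should correlate negatively with the mutant change. Across the called genes r was 0.13, which by the bound first set (above 0) argues against it, but 23 of 36 reassignments of the ratios within groups were as low, over a span of -0.56 to 0.63, and the Gapdh ratio gave -0.35, so that bound was too weak to decide and RNA quality and genotype cannot be told apart with 3 arrays a group. With the Actb ratio as a covariate the calls fell to 136. The median log2 size of the genes called without it moved from 0.54 to 0.49, and their median SE rose from 0.14 to 0.18.

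The atrial identity list was higher in 12-week mutants, by a median of 0.38, with 8 of 15 genes called higher and 1 lower. A larger atrial share of the tissue should raise abundant atrial transcripts alike, as seen for Myl4 (0.39 ± 0.12 SE), Myl7 (0.41 ± 0.13) and Nppa (0.38 ± 0.13), with Sln at 0.82 ± 0.16. Bmp10 rose by 1.11 ± 0.20 more than the mean of these 4, but it has the largest rise of the list, so its excess decides nothing and a larger atrial share stays open. With the Actb ratio as a covariate the median of the list was 0.28 (adjusted p = 0.0499) and with the Gapdh ratio 0.20 (adjusted p = 0.132), so a part from RNA quality stays open, while Bmp10 stood at 1.61 ± 0.21 without, 1.14 ± 0.20 with the Gapdh ratio (adjusted p = 0.019) and 1.20 ± 0.23 with the Actb ratio (adjusted p = 0.0336). An effect of the genotype on atrial genes stays an open, untested explanation.

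Of the 18 arrays 3 controls had a Xist signal above 1000, namely replicate 1 at 3 weeks (1450) and replicates 1 and 3 at 6 weeks (1381 and 1313). On the same arrays the Y-linked gene Eif2s3y stood at 838.6, 983.7 and 933.6, at or above the 82.9th percentile of all probe sets. These were the lowest Eif2s3y signals of the 18 arrays (next 1181.7), and so were those of the Y-linked Kdm5d, at 250.7, 310.2 and 218.9 (next 326.6). The percentile argues against hearts of females alone on these arrays. RNA from animals of both sexes on 1 array was not tested, and no biological explanation was tested, since the labels give no sex.

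With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. At 12 weeks 1 of 10 splits, the real one, gave as many genes, with 2128 against at most 3 in another split. Of the 4 splits that part all 3 same-numbered pairs the highest other gave 1, and the other 6 splits, which part 1 pair, gave up to 3. For controls at 12 against 6 weeks it was 1 of 10 (4450, highest other 0), and at 12 against 3 weeks 1 of 10 (4085, highest other 401). For mutants against controls at 3 and at 6 weeks, and for controls at 6 against 3 weeks, the real counts were 0, so all 10 of 10 splits gave as many, with a highest other of 0, 0 and 1.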

How the results depend on the processing

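The Actb covariate, leaving out the arrays with high Xist signal, averaging over 3 and 6 weeks, and leaving out both 3-week replicate 3 arrays were chosen after the data were seen. For 207 values of named genes and 45 list calls, an offset before the log2 transformation changed no call and no direction. The Gapdh ratio as a covariate ended 79 gene calls and 7 list calls, the Actb ratio 96 and 8, with 4 more gene calls ended by turning, quantile normalization 6 and 15, with 2 more list calls ended by turning, and an estimated correlation all 45 list calls. No named call of the average, the F test or the controls at 12 against 3 weeks held under every alternative, and 12 of 65 at 12 weeks did, Bmp10 among them. Lists were not run with robust estimation, which camera lacks, the average and the F test gave no value with only the groups compared, and the alternatives for Pitx2 were not run. Probe sets dim on average over all arrays were left out, so their changes are not covered. The mean of a kept gene in a group could still lie below the cut of about 103. At 12 weeks it did for Tigd5 (79.3 ± 68.3), 4833427F10Rik (57.7 ± 41.1) and Dhx38 (93.9 ± 22.7) in controls, and Sema4b (93.4 ± 56.8) in mutants. Between control ages it did for Apoc1 (58.2 ± 41.8) and Rhbdf2 (68.6 ± 44.5) at 12 weeks. At 3 weeks it did for Cep295 (68.6 ± 18.3) and Hspbap1 (80.8 ± 53.9) in controls. Where a value below differs, the cause was not tested unless stated.

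For the average, the count was 32 with no filter, 89 with the upper 30% filter (fewer genes tested), 29 with median centring, 18 with no trend, 270 with array weights, 17 with the replicate block, 36 with the Gapdh and 19 with the Actb covariate, 0 with the Xist covariate, 1 with high-Xist arrays left out and 4 over 3 and 6 weeks only. For the F test it was 310 with no filter, 189 with no trend, 1282 with array weights, 82 with the replicate block, and 0 with the Gapdh or Actb covariate (limma, 2793 at an unadjusted p under 0.05 without). At 3 weeks it was 6 with array weights, and at 12 weeks 182 (Gapdh) and 136 (Actb). For controls it was 1 at 6 against 3 weeks with median centring, the replicate block or the Actb covariate, 817 (Gapdh) and 0 (Actb) at 12 against 6 weeks, and 688 and 0 at 12 against 3 weeks. The replicate block ended 6 of 65 named calls at 12 weeks, 9 of 16 in the average, none of 4 in the F test and no list call. Genes shared at an unadjusted p under 0.01, in place of calls, were 22, 38 and 9 for 3 and 6, 3 and 12, and 6 and 12 weeks.

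Leaving out each array gave 0 to 19 genes at 3 weeks, 0 at 6 weeks, 803 to 2361 at 12 weeks, 13 to 155 for the average, 4 to 1001 for the F test, and for controls 0 to 1 at 6 against 3, 3319 to 4615 at 12 against 6 and 3048 to 4241 at 12 against 3 weeks.

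The direction reversed with the mean of probe sets for Tpm1 at 3 weeks (0.087), Sln at 6 weeks (-0.056), Vcl, Dsg2 and C1qb at 12 weeks (0.019, 0.093, -0.17), and Dsg2 and Rpl27 in the average (0.036, -0.010). With quantile normalization it did for Myl7 at 3 weeks (0.032) and the 6-week sarcomere and oxidative phosphorylation lists (medians -0.021 and 0.0092, the latter by its test). With the Actb covariate, for controls at 12 against 3 weeks, it did for Apoc1 (1.12), Rhbdf2 (0.17), Slc2a1 (-0.14) and Tnni2 (0.45). Without both 3-week replicate 3 arrays it did for Prc1 (-0.065) and the extracellular matrix and cell cycle lists (-0.048 and -0.065), and over 3 and 6 weeks only for Des (-0.18) and Rpl27 (-0.088). Leaving out each array, the 3-week median of the extracellular matrix list ranged from 0.026 (without replicate 3 of the 3-week controls, reversed in its test) to 0.585, and the 6-week median of the unfolded protein list from -0.075 (without replicate 3 of the 6-week mutants) to 0.154.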

Other observations

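The limit of 500 used here was chosen after the values were seen. Scgb1a1, the secretory protein of airway club cells, ranged from 1.9 to 4903 over the 18 arrays. It stood at 705 to 4903 on 10 arrays and at 1.9 to 28.7 on the other 8, and each set held arrays of all 6 groups. Scgb3a2, another airway secretory protein, stood at 249.7 to 2522 on the same 10 arrays and at 14.6 to 48.0 on the other 8. Sftpc, a surfactant protein of the alveoli, stood at 38.6 to 218 on these 10 arrays and at 23.1 to 105.5 on the other 8. Adipoq, a hormone of fat cells, stood at 1405 to 6427 on the 10 arrays and at 502 to 2230.5 on the other 8. The ranges of Sftpc and Adipoq overlap between the sets, but both reached higher values on the 10 arrays.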
